A study of Mus musculus with 2 samples.

How the data were processed

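Gene expression was measured in the kidney of 1 Mxi1 +/+ mouse (the control) and 1 Mxi1 -/- mouse (the experiment), both labelled 1Y, on 1 single-colour array each. Mxi1 encodes a partner of MAX that opposes MYC at shared DNA sites. Per the labels' protocols, total RNA was column-purified, treated with DNase, amplified and labelled as biotinylated cRNA with a kit made for CodeLink oligonucleotide arrays. The series text adds that bacterial control mRNA was used in the labelling.

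The deposited table holds 1 linear intensity per probe and array for 20289 probes. The software, background correction and normalization that made these intensities are not given in the sources used here. The values are decimals with a median of 0.929 in Mxi1 +/+ and 0.935 in Mxi1 -/-. The code -9999 stood in 60 places in Mxi1 +/+ and 39 in Mxi1 -/- and was read as a missing value. Values at or below 0 numbered 251 and 332, and the lowest were -0.168 and -0.236. The table carries no detection calls, so a noise floor was set for each array at 3 times the root mean square of its values below 0. It came to 0.102 in Mxi1 +/+ and 0.156 in Mxi1 -/-, with 10.3% and 15.7% of probes under it. Where 1 of the 2 values lies under its floor, a fold is given as a lower bound against that floor.

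A table of the platform's annotation named 1 gene for 10349 probes, with 10208 different symbols, and named no probe with several genes. All 10349 gene identifiers matched the mouse RefSeq gene table used for current symbols (assembly GRCm38.p6). The other 9940 probes are unnamed here, so a gene that is absent from the text may still be on the array. No coordinates are given, because the sources name no genome build for the probes.

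Intensities were converted to log2 without a pseudocount, and each array was centred on its median over the 19663 probes above 0 in both arrays. The other 626 probes were left out, and in none of the 549 left out for a value at or below 0 did the other array exceed 1. The difference is log2 of Mxi1 -/- minus log2 of Mxi1 +/+, so positive values are higher in Mxi1 -/-. A gene with several probes (136 genes) took the probe with the highest mean level, which left 9985 measured genes. Of these, 5737 had a mean level at or above the median of all probes and form the set in which folds were counted.

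With 1 mouse per genotype there is no replicate spread, so no p-value, standard error or count of significantly changed genes was computed. The 2-fold line is a rule of size. The only error estimate is technical and within arrays: in 42 genes with a pair of probes at or above the median level, the standard deviation of the log2 difference between probes of a gene was 0.165 per probe. It contains no variation between animals, dissections or hybridizations. The number of arrays limits the precision.

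Before the data were examined, 47 gene lists were fixed: the MYC network and its targets, kidney cell types, other cell types that the tissue could hold, injury, immunity, metabolism and signalling. The 46 lists with at least 4 measured genes were placed by their median among 10000 random lists of the same size, matched on mean level in 20 bins. A list is said to lie outside when its median falls beyond the central 95% of those random lists. This describes these 2 arrays and is not a test of genotype. The rule for named genes was fixed at the same time. It takes the MYC network, the 12 largest differences in each direction at or above the median level, up to 4 such members of each kidney cell list and each list outside, and a fixed set of kidney genes (Ren1, Egf, Umod, Havcr1, Lcn2, Spp1, Pkd1, Pkd2, Pkhd1, Ddx3y, Eif2s3y and Xist). Of that set, Egf, Havcr1, Pkd1, Pkhd1 and Eif2s3y had a named, measured probe.

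The procedure was tested on simulated data made by shuffling differences within level bins over the 9985 genes. With no effect, 14 of 230 list placements (6.09%) lay outside. Shuffling removes any tendency of a list's genes to move together, so this rate holds only for independent genes. With all MHC genes shifted by 0.5 or by 1 on the log2 scale, the MHC list lay outside in 5 of 5 simulations at each size. Of 500 simulated genes shifted by 1.5, 91.0% passed the 2-fold line, and all 500 shifted by 3 did. Alternatives were no centring, quantile normalization, lowess on level, a pseudocount, averaging of a gene's probes, other level filters and thresholds, and 4 other ways to place a list. Leaving out the centring shifts all genes alike, so it cannot move a list among random lists. Averaging touches only the 136 genes with several probes. A tally over alternatives counts both, so it overstates how far a placement was challenged. A floor for low values was added after the data were seen. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, statsmodels 0.14.6 (lowess) and matplotlib 3.10.9 were used.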

Results

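Kidney RNA from 1 Mxi1 +/+ mouse and 1 Mxi1 -/- mouse was compared on 1 array each, to describe the expression pattern that goes with loss of Mxi1. Across 19663 probes the log2 intensities of the 2 kidneys correlated at r = 0.946, and at r = 0.974 for probes at or above the median level (Pearson, across probes, which are not independent replicates). Among the 5737 genes at or above the median level, 92.3% lay within 1.5-fold of each other. In that set 32 genes were at least 2-fold higher and 80 at least 2-fold lower in the Mxi1 -/- kidney. This imbalance depended on the set and the line: 576 were higher and 558 lower with no filter on level, 17 and 18 at 3-fold, and 32 and 30 among unnamed probes at or above the median level at 2-fold. It remained with the level filter at the 75th percentile (10 higher and 35 lower) and at 1.5-fold (138 and 302). Each value below comes from 1 mouse, so no difference could be set against variation between animals and none carries a p-value.

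Mxi1 itself was lower in the library labelled Mxi1 -/-. Its probe (number 13348) read 4.31 in Mxi1 +/+ and 1.69 in Mxi1 -/-, a 2.54-fold difference (log2 -1.35), for which no spread between animals is available. The Mxi1 -/- reading was still above that array's median of 0.935. The sources do not give the deleted part of the gene or the place of the probe in it, so the reading checks the labels only in direction.

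Other members of the MYC, MAX and MXD network with readings above the floor stayed closer together. Over all 11 measured members, Mxi1 included, 6 were higher and 5 lower in Mxi1 -/-, with a median log2 difference of 0.0023 that lay inside the range of random lists (percentile 66.7). Myc, the growth-promoting transcription factor, read 0.543 in Mxi1 +/+ and 0.745 in Mxi1 -/- (1.37-fold). The obligate partner Max read 1.52 and 1.41, and the partner-like factor Mlx read 8.74 and 8.55. Among relatives of Mxi1, Mxd4 was 1.24-fold lower, Mxd3 was 1.72-fold lower, Mxd1 was 1.64-fold higher and Mnt read 0.355 in both kidneys. Mycl was 1.12-fold higher and Mlxipl 1.02-fold higher. Mycn, counted among the higher members, lay under the noise floor in both arrays, so it has no fold here.

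Genes known as MYC targets were slightly higher as a list, and none reached 2-fold. Of 21 measured members 13 were higher and 8 lower, with a median log2 difference of 0.09 (percentile 98.6). The largest on the higher side were 3 genes of ribosome and polyamine production. Nucleolin (Ncl) read 39.3 in Mxi1 +/+ and 63.6 in Mxi1 -/- (1.62-fold), fibrillarin (Fbl) read 8.01 and 12.8 (1.60-fold), and spermidine synthase (Srm) read 1.69 and 2.67 (1.59-fold). The co-chaperonin Hspe1 was 1.16-fold higher. Other genes of ribosome and polyamine production were lower: Npm1 1.24-fold, Odc1 1.21-fold and Nolc1, which lay below the median level, 1.64-fold. The list stayed outside under 5 of 10 alternatives, down to percentile 92.3. Cell cycle and DNA replication genes did not go with it: 17 of 23 were lower, with a median of -0.26 that lay inside the random range at percentile 2.82, and outside it under 3 of 10 alternatives, down to percentile 1.05. Cytosolic ribosomal protein genes had a median of -0.04 over 56 members (percentile 45.3).

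The group that stood furthest above its random range was the MHC list, whose products present peptides to T cells. All 10 measured members were higher in Mxi1 -/-, 6 of them at least 2-fold, and the median log2 difference of 1.45 exceeded all 10000 random lists. Among the 10, Tapbp read 0.12 and 0.15, the latter under the noise floor, so its direction is not resolved. H2-DMb1 and H2-DMa, the chains of the peptide loader of MHC class II, read 0.770 and 3.98 (5.17-fold) and 3.34 and 11.5 (3.45-fold) in Mxi1 +/+ and Mxi1 -/-. The class II chains H2-Eb1 and H2-Aa were 3.19-fold and 1.82-fold higher. Outside the naming rule and chosen after their values were seen, the class II transactivator Ciita (0.454 and 1.20) and the class I light chain B2m (243 and 360) also read higher.

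Interferon response genes were higher too. Of 18 measured members 16 were higher, 6 of them at least 2-fold, and 2 were lower. The lower members were Ifit2, at 2.03-fold, and Oas1a, under the floor in Mxi1 -/- and at least 1.17-fold lower. The median log2 difference of 0.56 again exceeded all 10000 random lists. The largest were the immunity-related GTPases Iigp1 (1.02 and 8.82, 8.68-fold) and Igtp (1.88 and 10.5, 5.56-fold), followed by the immunoproteasome subunits Psmb8 (3.38-fold) and Psmb9 (2.84-fold). Relatives outside the list were among the 12 genes furthest above the control kidney. The GTPase Tgtp1 read 4.67 and 48.1 (10.3-fold), the guanylate-binding protein Gbp8 was 6.50-fold higher and Irgm2 was 4.18-fold higher. Both lists stayed outside under all 10 alternatives.

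Lists of immune cell types were placed separately. The macrophage and monocyte list had a median of 0.23 (14 of 19 higher, percentile 99.3), with cathepsin S (Ctss) 1.67-fold, and the complement components C1qa 1.57-fold, C1qb 1.49-fold and C1qc 1.23-fold higher. The B cell and plasma cell list had a median of 0.42 (8 of 10 higher, percentile 98.9), with the IgE receptor Fcer2a at 2.15-fold, while the B cell receptor components Cd79b and Cd79a were 1.25-fold and 1.04-fold higher. Of its 4 members past 2-fold, 3 lay below the median level. The T cell and NK cell list lay inside its range (median 0.22, percentile 94.2) and above it under 1 of 10 alternatives. Neutrophil and mast cell genes also lay inside (median -0.10). Of 30 cytokine and chemokine genes 19 were higher (median 0.18, percentile 99.6). They included Ccl19, a chemokine of lymphoid tissue, which read 7.98 and 28.6 (3.59-fold), Cxcl10 (1.66-fold), Cxcl12 (1.36-fold) and Ccl5 (1.31-fold). The macrophage and B cell lists each stayed outside under 8 of 10 alternatives, and the cytokine list under 9.

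**Figure D1:**
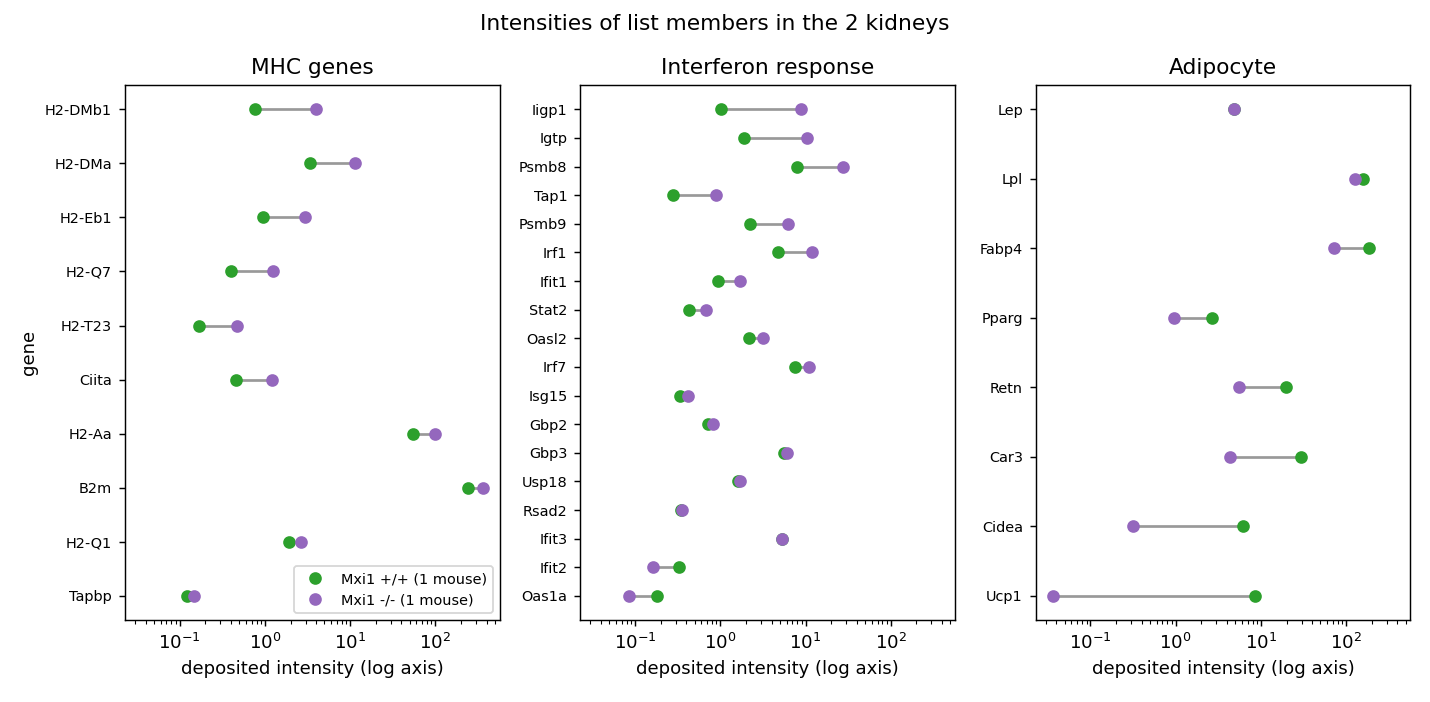
Deposited intensity (log axis, 1 mouse per genotype, no error bars) of each measured member of the MHC, interferon response and adipocyte lists, with Mxi1 +/+ in green and Mxi1 -/- in purple. All 10 MHC genes read higher in Mxi1 -/-, although Tapbp lay under the noise floor there, and all 8 adipocyte genes read lower, Lep by 1.01-fold.

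The group furthest below its random range was the adipocyte list. All 8 measured members were lower in Mxi1 -/-, 6 of them at least 2-fold, and the median log2 difference of -1.64 lay below all 10000 random lists, also under all 10 alternatives. Cidea, a lipid droplet protein of brown fat, read 6.20 in Mxi1 +/+ and 0.312 in Mxi1 -/- (19.9-fold lower). Carbonic anhydrase 3 (Car3) was 6.75-fold lower, the adipokine resistin (Retn) 3.55-fold lower, and Pparg, the master regulator of fat cells, 2.75-fold lower. Outside the naming rule and chosen after its values were seen, Ucp1, the uncoupling protein of brown fat, read 8.52 in Mxi1 +/+ and lay under the floor in Mxi1 -/-, at least 54.6-fold lower. Leptin (Lep) read 4.86 and 4.83. Genes known from fat cells also stood among the 12 furthest below the control kidney. The lipogenic regulator Thrsp was 6.26-fold lower, the melanocortin receptor accessory protein Mrap 4.78-fold, the adipocyte galectin Lgals12 3.73-fold and the lipid droplet protein Plin4 3.71-fold lower.

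A further 4 of these 12 genes are known from stratified epithelia, for which no list was fixed. Sprr1a read 11.5 and 2.29 (5.03-fold lower), Sprr2a1 was 4.91-fold lower, the basal keratin Krt5 read 3.30 and 0.684 (4.82-fold lower), and the epithelial surface protein Ly6d was 4.61-fold lower. The tubular injury list, which is rich in epithelial keratins and annexins, had a median of -0.35 (9 of 13 lower, percentile 0.28). Krt19 was 3.43-fold, Krt20 1.69-fold, Anxa3 1.53-fold and Anxa1 1.28-fold lower, while Havcr1, the injury marker KIM-1, read 1.38 and 1.67. That list stayed outside under 8 of 10 alternatives.

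**Figure D2:**
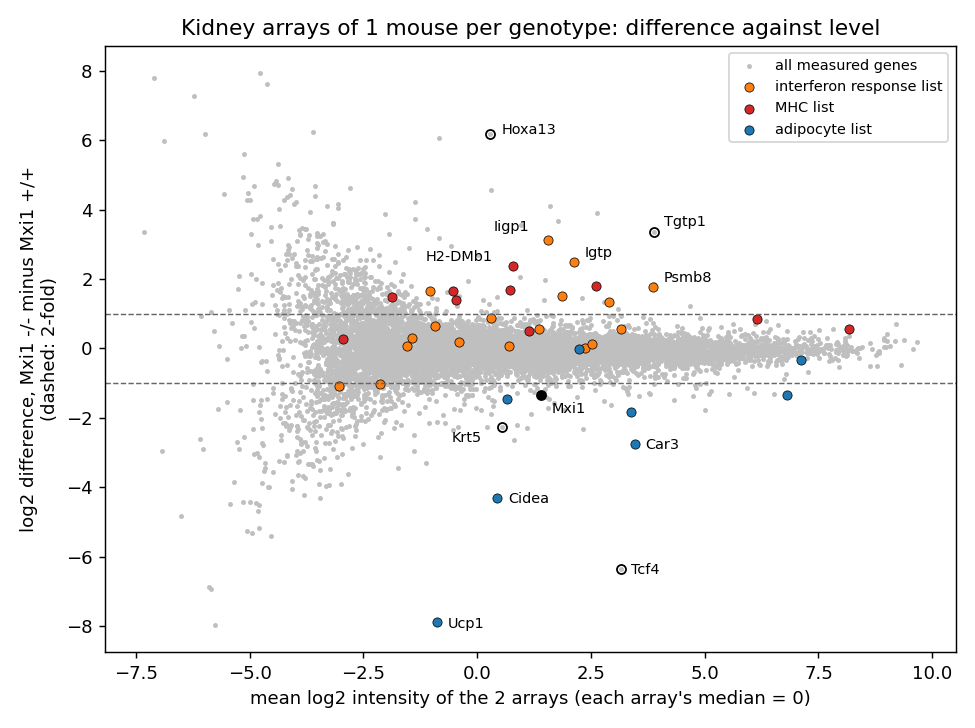
Log2 difference (Mxi1 -/- minus Mxi1 +/+) against the mean log2 intensity for the 9985 measured genes, with members of 3 lists in colour, Mxi1 as a filled black point and other named genes circled. Dashed lines mark 2-fold. Differences widen at low intensity, where 36.4% of the dimmest 2497 genes lie past 2-fold against 1.48% of the brightest 2496.

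The remaining extremes were single genes. Tcf4, a helix-loop-helix transcription factor, read 82.2 in Mxi1 +/+ and 1.00 in Mxi1 -/- (81.9-fold lower). The homeobox gene Hoxa13 read 0.147 and 10.6 (72.0-fold higher), and the olfactory receptor Olfr907 read 0.261 and 6.12 (23.5-fold). Both folds rest on low Mxi1 +/+ readings. With a pseudocount of the array median, their log2 differences fell from 6.17 to 3.41 and from 4.55 to 2.56. The potassium channel Kcnn2 was 17.3-fold, the splicing factor Lsm5 15.1-fold, the cartilage matrix protein Chad 12.8-fold and the T-box factor Tbx20 11.8-fold higher. Chad and Kcnn2 sit on consecutive probe numbers, 12606 and 12607, and each of these genes rests on a single probe per array.

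Most collecting duct genes were lower. Of 11 principal cell genes 8 were lower and 3 higher, with a median of -0.33 (percentile 0.51, outside under all 10 alternatives). The keratin Krt18 was 2.36-fold lower, Tmem45b read 67.8 and 38.1 (1.78-fold lower), the vasopressin receptor Avpr2 was 1.27-fold lower and Fxyd4, a regulator of the sodium pump, 1.26-fold lower. The higher principal cell genes were Hsd11b2 at 1.15-fold, Scnn1g at 1.03-fold and Aqp3 at 1.01-fold. Of 10 intercalated cell genes 9 were lower (median -0.35, percentile 0.66, outside under 7 of 10 alternatives). The chloride-bicarbonate exchanger Slc26a4 was 1.49-fold, Kit 1.45-fold, the transcription factor Foxi1 1.31-fold and Slc4a9 1.30-fold lower. The list of solute and water transport regulators was lower in 13 of 14 members (median -0.39, percentile 0.16, outside under all 10 alternatives). Among them the urea transporter Slc14a2 was 1.64-fold, the sodium pump subunit Atp1b1 1.38-fold and the kinase Sgk1 1.35-fold lower.

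Other nephron segments went different ways. In the thick ascending limb list 5 of 7 genes were lower (median -0.37, percentile 0.81, outside under 7 of 10 alternatives): the potassium channel Kcnj1 was 1.57-fold, Ptger3 1.33-fold and the claudins Cldn10 and Cldn19 each 1.30-fold lower, while Egf was 1.31-fold higher. In the distal convoluted and connecting tubule list 5 of 8 were higher (median 0.15, percentile 97.6, outside under 4 of 10 alternatives), with the calcium binder Calb1 at 1.24-fold, the sodium chloride cotransporter Slc12a3 at 1.20-fold, Klk1 at 1.15-fold and Pvalb at 1.06-fold. The largest difference in that list was on the lower side, with Trpm6 at 1.34-fold lower, and S100g and Kl were 1.06-fold and 1.03-fold lower. Proximal tubule genes lay inside the random range, with 16 of 27 higher, none past 2-fold and a median of 0.0080 (percentile 88.9). Their extremes were Napsa (473 and 770, 1.63-fold higher), Dpep1 (1.51-fold higher), Gatm (1.55-fold lower) and Slc3a1 (1.42-fold lower). Podocyte genes also lay inside (median -0.03), with Dach1 at 1.97-fold higher, Cdkn1c at 1.76-fold lower, Plce1 at 1.13-fold and Wt1 at 1.11-fold higher. With its probes averaged, Plce1 was lower (log2 -0.28 in place of 0.17). Genes of cystic kidney disease and the cilium had a median of -0.14 (12 of 17 lower, percentile 17.7). Among them the autosomal recessive gene Pkhd1 read 1.75 and 1.71, and Pkd1 read 0.417 and 0.306.

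**Figure D3:**
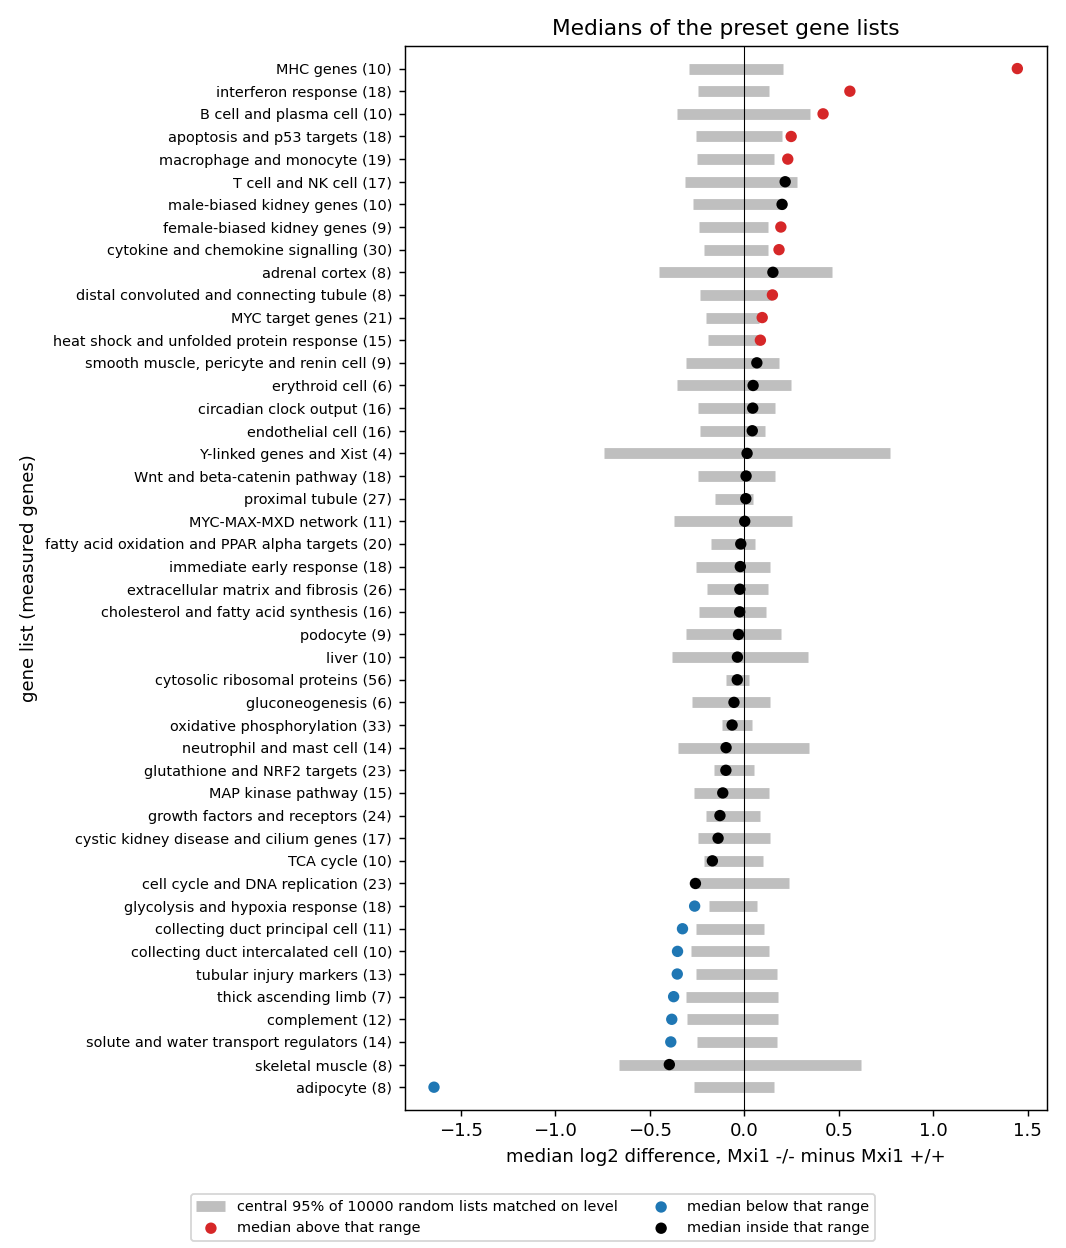
Median log2 difference (Mxi1 -/- minus Mxi1 +/+) of each of the 46 preset lists (points, number of measured genes in brackets) over the central 95% of 10000 random lists matched on level (grey bars). Of these, 10 lie above the bar and 8 below it, with MHC genes at 1.45 and adipocyte genes at -1.64 furthest out.

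In all, 18 of the 46 lists lay outside, where 2.3 would be expected by chance for independent genes. Glycolysis and hypoxia genes were lower in 16 of 18 members (median -0.26, percentile 0.24, outside under all 10 alternatives). Aldolase A (Aldoa) read 43.6 and 21.2 (2.05-fold lower), Hmox1 was 1.77-fold, Ndrg1 1.76-fold and pyruvate kinase (Pkm) 1.41-fold lower. Complement genes were lower in 7 of 12 members (median -0.38, percentile 0.63, outside under 7 of 10 alternatives), with C3ar1 at 1.70-fold, C2 at 1.60-fold, Cd55 at 1.38-fold and factor B (Cfb) at 1.34-fold lower. Among its higher members C4b was 1.77-fold, C1ra 1.47-fold, C5ar1 1.27-fold and C1s1 1.11-fold higher. The higher C1q genes were counted in the macrophage list. Over the alternatives the median rose as far as -0.11 and the percentile as far as 31.4, so complement was not lower as a whole. Heat shock and unfolded protein response genes were higher in 10 of 15 (median 0.09, percentile 98.4, outside under 8 of 10 alternatives), with the endoplasmic reticulum chaperones Sdf2l1 and Hsp90b1 at 1.65-fold and 1.60-fold, Pdia4 at 1.29-fold and Hspb1 at 1.27-fold. The lower members were Hsph1 at 1.35-fold, Dnajb1 at 1.31-fold, Herpud1 at 1.11-fold, Hspa8 at 1.09-fold and Calr at 1.08-fold. Apoptosis and p53 target genes were higher in 13 of 18 (median 0.25, percentile 99.0, outside under 5 of 10 alternatives), with Gadd45a at 1.27-fold, Sesn2 at 1.20-fold, Cdkn1a at 1.08-fold and Bak1 at 1.05-fold. The largest differences among members at or above the median level were lower: Perp 1.57-fold, Pmaip1 1.33-fold and Ccng1 1.31-fold. With only members at that level the list's median was 0.07, so dim members carry much of the reported median.

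Lists that track the sex of the animal did not separate the 2 kidneys in opposite directions. The female-biased list was higher in 7 of 9 members (median 0.19, percentile 99.6, outside under 9 of 10 alternatives), with Abcc3 at 1.40-fold, Ttc36 at 1.20-fold and Slc7a12 at 1.14-fold, and it shares Napsa with the proximal tubule list. The male-biased list was higher in 7 of 10 (median 0.20, percentile 97.2) and lay inside its range, but above it under 4 of 10 alternatives. With only its members at or above the median level its median was -0.10, inside the range. The Y-linked gene Eif2s3y read 0.166 in Mxi1 +/+ and 0.109, under the floor, in Mxi1 -/-. Lists that lay inside their ranges included endothelial genes (median 0.04), smooth muscle and renin cell genes (0.07), extracellular matrix and fibrosis genes (-0.02), oxidative phosphorylation (-0.06), the TCA cycle (-0.17), fatty acid oxidation (-0.02), MAP kinase genes (-0.11), Wnt genes (0.0094), circadian output genes (0.04), immediate early genes (-0.02), adrenal cortex genes (0.15), skeletal muscle genes (-0.40), liver genes (-0.04), erythroid genes (0.05), gluconeogenesis (-0.05), cholesterol and fatty acid synthesis (-0.02), glutathione and NRF2 targets (-0.10), growth factors and receptors (-0.13) and the 4 measured Y-linked genes (0.01). Median and mean had opposite signs in 8 of the lists inside their ranges (proximal tubule, endothelial, smooth muscle, neutrophil and mast cell, erythroid, Y-linked, circadian and Wnt), and in none of the lists outside. Some lists inside their ranges as reported went outside under alternatives: endothelial genes above the range under 3 of 10 (up to percentile 99.3), the TCA cycle below it under 1 of 10 and skeletal muscle below it under 1 of 9. Smooth muscle and renin cell genes turned to a median of -0.34, below the range (percentile 1.57), with only their members at or above the median level. The metallothionein list had 1 measured gene, the zinc exporter Slc30a1, at -0.29.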

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

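Mxi1 was lower under each alternative run on it. Its log2 difference stayed between -1.36 (noise floor) and -1.31 (lowess) except with a pseudocount of the array median, which shrinks differences by construction and moved it to -1.01. The number of genes past the line of size, 112 as reported, was 112 without centring, 105 after quantile normalization, 109 after lowess, 113 with probes averaged and 122 with the floor, which was added after seeing the data. It was 70 with the pseudocount, 1134 with no level filter, 45 with the filter at the 75th percentile, 440 at 1.5-fold and 35 at 3-fold. The share of higher genes among them, 28.6% as reported, was 50.8% with no filter and 48.6% at 3-fold. Each of the 24 largest named differences stayed past 2-fold in its direction under all 6 alternatives run on them. Between 12 and 20 lists lay outside under the 10 alternatives, and 10 to 18 of the reported 18 were among them. Of 455 placements of lists under alternatives 35 lost and 14 gained a place outside, and no list that lay outside changed direction. Among the 14 are smooth muscle and renin cell genes, inside as reported (0.07), which turned to -0.34 with only members at or above the median level. Of 660 values of single genes 46 moved by more than the spread between probes, 43 of them with the pseudocount, and no gene past 2-fold changed direction. Below 2-fold, Plce1 turned from 0.17 to -0.28 with its probes averaged, and Mnt and Mlx, both near 0, changed sign under some scalings. No paired analysis was possible because each genotype has 1 mouse, and leaving out a mouse leaves no comparison. No detection calls came with the intensities, so folds of dim genes are the least certain. The cause of these changes was not tested beyond the construction of each alternative.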

Other observations

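The test of neighbouring probe numbers below, and the split of antiviral genes from the interferon list, were chosen after the results were seen. The other lists below were written after the preset lists had been seen and before their own genes were looked at. In a fresh list of 19 measured interferon-gamma-inducible genes 12 were higher and 7 lower in Mxi1 -/-. Chosen after their values were seen, the proteasome subunit Psmb10 read 5.82 and 11.1, the peptide transporter Tap2 read 5.31 and 9.21, the class I gene H2-M3 read 3.57 and 6.08, and the checkpoint ligand Cd274 read 0.897 and 1.57. On the lower side Ido1 read 0.272 in Mxi1 +/+ and lay under the floor in Mxi1 -/-, Gbp5 read 0.535 and 0.444, Wars read 1.22 and 1.08, and the proteasome activator Psme1 read 24.2 and 22.8. Socs1, H2-Oa and Gbp2b were also lower, by 1.10-fold or less. Antiviral interferon-stimulated genes had a median of 0.07 over 9 genes, 7 higher and 2 lower (percentile 79.1). Chosen after their values were seen, Ifit3 read 5.29 and 5.34 and Usp18 read 1.61 and 1.69, while Oasl2 read 2.16 and 3.20. The other higher genes were Ifit1 at 1.82-fold, the largest rise in the list, Irf7 at 1.46-fold, Isg15 at 1.23-fold and Rsad2 at 1.04-fold. The lower genes were Ifit2, which read 0.331 and 0.163, and Oas1a, which read 0.183 in Mxi1 +/+ and lay under the floor in Mxi1 -/-.

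In the stroma, some matrix genes went opposite ways while their list lay inside the random range. Periostin (Postn) read 1.14 and 0.265, versican (Vcan) 0.994 and 0.395 and lumican (Lum) 2.91 and 1.19, all lower in Mxi1 -/-, whereas matrix Gla protein (Mgp) read 63.8 and 109. Among endothelial genes Pecam1 read 1.43 and 0.555 and endomucin (Emcn) 18.6 and 10.7, while Kdr read 9.86 and 12.8. These genes were chosen after their values were seen.

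The higher readings of MHC and interferon-inducible genes in Mxi1 -/- do not follow from a trend with signal level alone, since the MHC median was 1.39 after lowess against 1.45 before. A general rise of leukocytes in the Mxi1 -/- piece, as the whole cause, is argued against by a leukocyte list with a median of 0.21 over 18 genes. Its 95% bootstrap interval over genes was -0.04 to 0.58. That is below 0.723, a fraction of the MHC median set beforehand as the least this explanation needs. The list had 13 genes higher and 5 lower and lay just inside its random range (percentile 96.8). Most of its genes lie below the median level, and it does not address a rise of antigen-presenting cells alone. A smaller contribution stays open, since the macrophage and B cell lists lay above their random ranges. The interferon-gamma list holds antigen-presentation genes such as Tap2, H2-M3, H2-Oa and H2-DMb2, so it is not independent of the MHC list. Its median was 0.49, above all 10000 random lists, although its bootstrap interval ran from -0.09 to 0.77. A response of the interferon-gamma kind is therefore only a hypothesis. Whether this follows from the genotype or from the state of a single mouse (an infection, for example) cannot be told apart with 1 mouse per genotype.

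Lower fat genes, and the lower genes known from stratified epithelia, may reflect what was dissected with the Mxi1 +/+ kidney. For adipose tissue, a second list of adipocyte genes had a median of -0.36 over 16 genes (bootstrap interval -0.55 to -0.09, percentile 0.20), lower than random lists but short of the -0.5 set beforehand, and several of its genes are also used by kidney cells. For urothelium, the median was -0.22 over 14 genes (bootstrap interval -0.55 to -0.01, percentile 5.84), with Krt23 at 1.81 and 0.555 but Upk1b, a urothelial plaque protein, at 9.77 and 10.0. Genes of that list shared with stratified epithelia went both ways: Trp63 read 0.387 in Mxi1 +/+ and lay under the floor in Mxi1 -/-, Krt14 read 0.358 and 0.322, Pkp1 read 4.52 and 4.70, and Krt6a read 1.91 and 2.23. No list of stratified epithelial genes was tested, so Sprr1a, Sprr2a1, Krt5 and Ly6d, chosen by the size of their difference, stand alone. A trend with signal level is argued against for the fat genes, whose preset median was -1.61 after lowess. Both tissue explanations stay open, as does an effect of the genotype.

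At or above the median level 22 probes differed by 8-fold or more, 20 of them higher in Mxi1 -/-, and 12 of those 20 are unnamed. Of the 8 named ones 1 belongs to a preset list. Chad and Kcnn2, on consecutive probe numbers, prompted a test of blemishes on the array surface as a candidate explanation. Among the other 20 probes 1 pair lies within 5 probe numbers, inside the central range of 0 to 1 in 10000 random draws. The mean of those draws was 0.10 pairs. The count did not exceed that range, so the test did not show that these jumps cluster. No count can fall below a range that starts at 0, so it cannot exclude clustering either. Probes 12633 and 12667, also higher in Mxi1 -/-, lie near Chad and Kcnn2 but beyond the window of 5. Isolated blemishes would leave no pairs, and the sources used here do not say that probe numbers follow the layout. Whether the jumps are technical stays open.

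Among unnamed probes at or above the median level 32 were at least 2-fold higher and 30 at least 2-fold lower. The extremes were probe 12633 (0.190 and 95.6) and probe 12382 (at least 137-fold higher in Mxi1 -/-), and on the other side probe 13583 (58.1 and 9.66) and probe 9413 (13.2 and 2.49).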
